A study of Rhodopseudomonas palustris CGA009 with 14 samples.

How the data were processed

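RNA was measured in 14 samples of R. palustris CGA009, 2 at each of 0, 12, 30, 50, 90, 140 and 180 h after the headspace was flushed with argon. The authors made libraries from total RNA with primers selective for this organism and a low-input multiplex kit. Reads were aligned with BWA and DESeq was used, per the submitters' processing notes. Their versions, the genome build, the strand setting and the treatment of reads that match several copies are not given in the sources used here. Per the file headers each table holds raw read counts (unit: counts) and RPKM for every gene and for the intergenic stretch upstream of it. The counts were whole numbers, and the RPKM values, made by the authors from counts, feature size and the library's total, were used only to check the counts. The totals implied by the RPKM were 0.999 of the table totals. Coordinates were not used.

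Each table had 4893 genes and as many intergenic stretches. The 49 tRNA and 8 rRNA genes were left out of all tests, which left 4836 genes, of which 4818 passed the filter of edgeR (filterByExpr). tRNA took 0.497 to 1.53% of genic reads. Gene names and products are those in the tables, since the locus tags of the other annotation did not match them. Most gene sizes are multiples of 3 (99.7%), so sizes are coding lengths. Library totals ran from 6299748 to 8260800 reads. Intervals from counting alone were not used, because reads without molecular identifiers are not independent molecules.

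Counts were fitted in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1: TMM scaling (factors 0.853 to 1.18), 1 mean per time over all 14 libraries, robust quasi-likelihood dispersion (biological coefficient of variation 0.148, 7 residual degrees of freedom) and two-sided quasi-likelihood F tests. Contrasts were each starved time against 0 h, each time against the one before, and all times together, with Benjamini-Hochberg adjusted p under 0.05. SE is the absolute log2 change divided by the root of F. CPM are TMM-scaled, with SD over 2 libraries. The samples were grouped by time alone, without a replicate block. Alternatives were other scaling (DESeq2 1.42.0 with its own test, RLE), no filter or a strict one (10 CPM in 2 libraries), a minimum fold of 1.5, the compared libraries alone, a replicate block and leaving out each library in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

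The fit, the contrasts, the alternatives just named, 29 gene lists, search patterns for their members and the rule for named genes were fixed before the data were examined. After the tables were seen, but before any test, 72 wrong matches were removed and 7 missing subunits added in 18 lists from product names alone, such as isopropylmalate synthase matched as malate synthase. The lists as first matched, library size alone as scaling, tests without rnpB, list tests with each library left out, an exact permutation test of the pathway difference over all times, and that difference with each shunt gene alone were added after seeing the data. 28 lists with at least 3 measured members were tested at 6 times (168 tests) with camera, which asks whether a list's genes moved more than others, with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Named genes were all glyoxylate shunt members, TCA cycle members past the test, the 6 largest rises and falls per time against 0 h and 3 per step among called genes with a mean of at least 20 CPM whose libraries lay beyond those compared, and the 4 members of each other list with the smallest p over the time course, plus nifH, nifD and nifK. Of these 173 genes the text gives a selection. The contrast between pathways is each library's mean log2 CPM (prior count 2) of the TCA cycle list minus that of the shunt list.

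The method was tested on simulated data with the spread of these libraries, 5 runs of 200 changed genes each. For 180 h against 0 h it recovered 21.2% of genes changed 1.5-fold, 77.6% changed 2-fold and 97.0% changed 4-fold, with 27 false calls among 22986 unchanged genes. A list of 20 genes changed 1.5-fold passed in 5 of 5 runs and an unchanged list in 0. Changes of 1.5-fold were therefore often missed in these runs, where few of the genes changed. At 12 h 3335 genes passed against 0 h, and the Benjamini-Hochberg cutoff is less strict where more genes change. The recovered shares and false calls therefore do not describe the comparisons with 0 h. Simulated genes also varied independently of each other. In the real list tests the estimated inter-gene correlation ran from -0.16 to 0.68, with a median of 0.13. The simulated lists therefore do not show how often the real list tests pass falsely.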

Results

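Transcript levels were measured by RNA sequencing in Rhodopseudomonas palustris CGA009, a purple bacterium that grows anaerobically in light and makes hydrogen gas as a product of nitrogenase. Cells had grown on acetate with nitrogen gas as their only nitrogen source until an argon flush removed that gas (0 h), and were sampled again after 12, 30, 50, 90, 140 and 180 h of nitrogen starvation. Each of the 7 times had 2 libraries, 14 in all. The tables held between 6299748 and 8260800 reads per library, of which 4847663 to 5934285 lay in annotated genes, and the median gene had 234 to 395 reads. All levels are relative abundances, in CPM (counts scaled to a common library size), so the amount of RNA per cell is not known. The sources used here do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. The share of genic reads from rnpB, the RNA of ribonuclease P, went from 1.60% ± 0.0616 at 0 h to 7.72% ± 0.153 at 180 h (SD, n = 2).

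The comparison of each starved time with 0 h asks which genes differ once nitrogen gas is gone. At 12 h 14 of 16 genes of the photosynthetic reaction centre and antennae, 10 of 10 of ATP synthase, 24 of 28 of respiratory complex I and 45 of 55 of the ribosome had fallen, and 26 of 32 genes of the molybdenum nitrogenase cluster had risen. Of 13 genes of the vanadium and iron nitrogenases 11 had risen at 12 h and 13 at 180 h. The gene of isocitrate lyase, the first enzyme of the glyoxylate shunt, was below its 0 h level at 30 and 50 h and above it from 90 h, though the 30, 50 and 90 h calls were each lost without some single library. In the same cells 12 of 16 genes of the tricarboxylic acid (TCA) cycle had fallen at 12 h and 14 at 180 h. Of 4818 genes tested with the edgeR quasi-likelihood test, 1733 were higher and 1602 lower at 12 h than at 0 h at a Benjamini-Hochberg adjusted p under 0.05. The counts higher and lower were 1744 and 1675 at 30 h, 1754 and 1745 at 50 h, 1789 and 1713 at 90 h, 1758 and 1751 at 140 h, and 1721 and 1774 at 180 h. The number of called genes that differed from 0 h by over 4-fold went from 595 at 12 h to 803 at 180 h. Gene changes are log2 fold changes from 0 h unless another time is named, so 0 is the 0 h level. In the counts of a gene list, the numbers in parentheses are those that rose and fell when p was adjusted over the list alone. Over the whole time course 4161 genes changed. Scaling by library size alone, without TMM factors, moved the median log2 change of all genes by up to 0.25, so smaller changes depend on the scaling. The near-even counts depend on it too, with 1920 higher and 1456 lower at 30 h, 1953 higher and 1533 lower at 50 h, 1458 higher and 1956 lower at 140 h and 1390 higher and 2047 lower at 180 h under that scaling. With a minimum fold of 1.5 the counts higher and lower were 1102 and 1088 at 12 h and 1141 and 1163 at 30 h. They were 1189 and 1279 at 50 h and 1219 and 1246 at 90 h. At 140 h they were 1193 and 1275, and at 180 h 1197 and 1275.

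**Figure D1:**
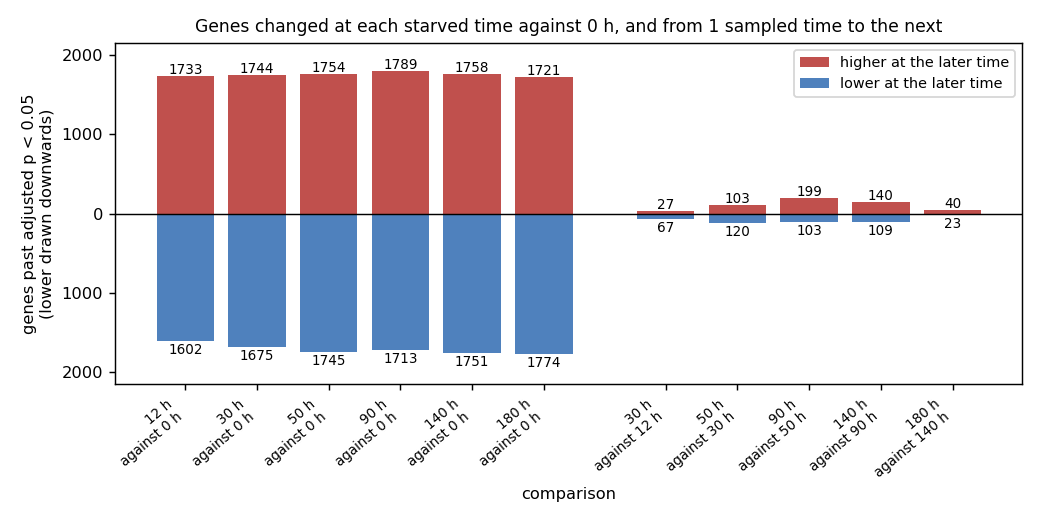
Number of genes (y axis) higher or lower in each comparison (x axis), each starved time against 0 h and each time against the one before, by the edgeR quasi-likelihood test at an adjusted p under 0.05. The counts against 0 h lie between 1602 and 1789 per direction, and the largest between neighbouring starved times is 199.

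The series title names a shift from the glyoxylate shunt to the TCA cycle, so both pathways were compared first. The shunt, which lets cells build biomass from acetate, has 2 genes in the tables. Isocitrate lyase (aceA, RPA4394) stood at 2978 ± 1217 CPM at 0 h, 1609 ± 55.5 at 30 h, 1534 ± 134 at 50 h, 5405 ± 1535 at 90 h, 9014 ± 568 at 140 h and 6641 ± 820.1 at 180 h (SD, n = 2). Its log2 change from 0 h was 0.23 (SE 0.29) at 12 h, where it did not pass. It fell to -0.89 (SE 0.29) at 30 h and -0.96 (SE 0.29) at 50 h, and was 0.86 (SE 0.29) higher at 90 h, 1.60 (SE 0.29) at 140 h and 1.16 (SE 0.29) at 180 h. Malate synthase (glcB, RPA4216), the second shunt enzyme, fell at all 6 times, with log2 changes between -1.33 and -1.14. The 0 h libraries differed in aceA (3838 and 2117 CPM), and its early and 90 h calls each hung on single libraries. The 30 h call was lost without 0 h replicate 1 (log2 change -0.39) or 30 h replicate 1 (-0.86), the 50 h call without 0 h replicate 1 (-0.46) or 50 h replicate 1 (-0.89), and the 90 h call without 0 h replicate 2 (0.48) or 90 h replicate 2 (0.54). With a minimum fold of 1.5 none of these 3 calls held, and the 90 h call was also lost with the 0 and 90 h libraries alone (0.84).

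Among the 16 TCA cycle genes, sdhB, sucC, sdhA and sucD had the largest falls at 12 h. At 12 h the log2 change was -3.07 (SE 0.17) for sdhB (RPA0216) and -2.22 (SE 0.14) for sdhA (RPA0217), which encode succinate dehydrogenase, and -2.46 (SE 0.16) for sucC (RPA0191) and -2.18 (SE 0.15) for sucD (RPA0190), which encode succinyl-CoA synthetase. At 180 h these were -2.71, -1.92, -2.36 and -2.19. Isocitrate dehydrogenase (idh, RPA3834), which competes with aceA for isocitrate, fell to -1.87 at 12 h and stood at -1.17 at 180 h. Aconitase (acnA, RPA0202) fell to -1.26 at 12 h and stood at -1.39 at 180 h. Fumarases fumC2 (RPA3500) and fumA (RPA3876) fell to -2.15 and -1.02 at 12 h, whereas fumC1 (RPA1329), at only 7.76 ± 1.71 CPM at 0 h (SD, n = 2), rose by 2.18. Smaller falls at 12 h were -1.18 for sdhD, -0.89 for sdhC, -0.76 for sucB and -0.72 for RPA3756, a malate dehydrogenase-like gene. By 180 h malate dehydrogenase (mdh, RPA0192) had fallen to -1.76 and citrate synthase (cisY, RPA2907) to -0.70, while 2-oxoglutarate dehydrogenase E1 (sucA, RPA0189) had a log2 change of 0.14 and did not pass. At 12 h 1 rose, 12 fell and 3 did not pass (1 and 12 adjusted over the list alone). At 180 h 1 rose, 14 fell and 1 did not pass (1 and 14 adjusted over the list alone). As a list the cycle fell at all 6 times, with camera adjusted p = 0.000494 at 12 h and 0.00530 at 180 h, but adjusted p = 0.241 and 0.307 with an estimated correlation. The sucB call at 180 h (log2 change -0.47) was lost without 180 h replicate 2 (-0.41). At 140 h sucA was 0.48 higher, a call lost without 0 h replicate 1 (0.44), without 140 h replicate 2 (0.46) or with library size alone (0.30). With a minimum fold of 1.5 the calls of RPA3756, sdhC and sucB at 12 h and of cisY, sdhD and sucB at 180 h did not hold.

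Set against each other, the pathways moved in ways that depend on the shunt gene. Against the mean of both shunt genes, TCA cycle transcripts gained at no starved time by more than the SD of the 0 h libraries. The mean log2 CPM of the 16 TCA genes minus that of the 2 shunt genes was -1.92 ± 0.39 at 0 h, -2.57 ± 0.21 at 12 h, -1.90 ± 0.01 at 30 h and -1.90 ± 0.01 at 50 h (SD, n = 2). It was -2.79 ± 0.09 at 90 h, -3.06 ± 0.05 at 140 h and -2.93 ± 0.03 at 180 h (SD, n = 2). The differences from 0 h were -0.66, 0.02, 0.01, -0.87, -1.14 and -1.01 in the order of the times. Those at 12, 90, 140 and 180 h, all negative, exceeded that SD, and those at 30 and 50 h did not. Single times were not tested, and an exact two-sided permutation test of 2 libraries against 2 cannot go below 0.333. The SD pooled over the 7 times was 0.17. All 7 times together differed (p = 0.00301, exact permutation test over the 135135 ways to split the 14 libraries into pairs), a test added after the values were seen that does not say which times differ. The negative differences rest on aceA. With aceA alone as the shunt, also a choice made after the values were seen, they were -1.42, -0.22, -0.14, -1.88, -2.62 and -2.28 in the order of the times (SD at 0 h 0.56, n = 2). With glcB alone, which fell slightly more than the TCA mean, they were 0.11, 0.26, 0.17, 0.14, 0.34 and 0.25 (SD at 0 h 0.23, n = 2), and the times together did not pass (p = 0.178, exact permutation test). Leaving out 0 h replicate 1 or 0 h replicate 2 moved the 12 h difference to -0.93 or -0.38, the 30 h difference to -0.26 or 0.30, and the 50 h difference to -0.26 or 0.29. As a log2 ratio of summed CPM, in which abundant genes weigh most, it was -1.20 at 12 h, -1.83 at 90 h, -2.30 at 140 h and -2.11 at 180 h. With both lists as first matched by name, before isopropylmalate synthases and other wrong matches were removed, the 6 differences were -1.19, -0.95, -1.19, -1.59, -1.48 and -1.36. Transcript levels do not measure the flux through either pathway.

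**Figure D2:**
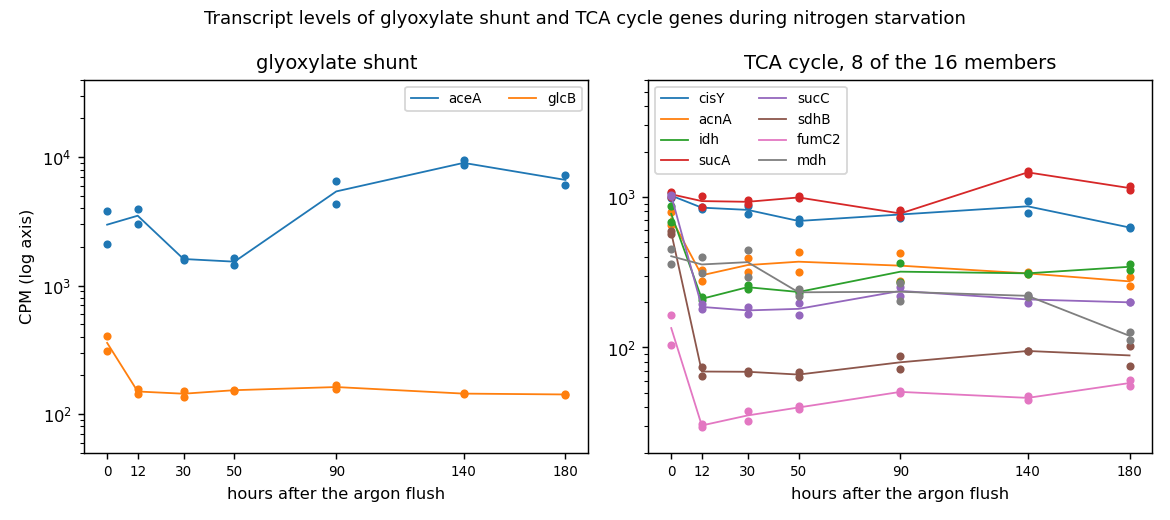
Transcript levels (CPM, log axis) against hours of nitrogen starvation for the 2 glyoxylate shunt genes and for 8 of the 16 TCA cycle genes. Points are the 2 libraries at each time and lines join their means: aceA ends at 6641 CPM against 2978 at 0 h, and sdhB at 88.5 against 579.

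Routes into and around both pathways were compared as well. The gene of the E1 beta subunit of pyruvate dehydrogenase, RPA2866, fell to -1.39 at 12 h and to -3.08 at 180 h, and RPA2863, a dihydrolipoamide dehydrogenase, to -2.15 and -2.69. Of the 14 genes of anaplerosis and gluconeogenesis, which link the TCA cycle to sugars, 1 rose, 8 fell and 5 did not pass (1 and 8 adjusted over the list alone) at 12 h. At 180 h 2 rose, 11 fell and 1 did not pass (2 and 11 adjusted over the list alone). The list fell with camera adjusted p = 0.0337 at 12 h and 0.00536 at 180 h, or adjusted p = 0.307 and 0.234 with an estimated correlation. The 12 h call was lost without 0 h replicate 1 (adjusted p = 0.0572) or 12 h replicate 1 (0.0523). Among the 5 genes of acetate activation, which make acetyl-CoA from acetate, the acetyl-CoA synthetases RPA4504 and RPA0211 fell to -2.38 and -1.49 at 180 h, and acetate kinase (ackA) had a log2 change of 0.23 and did not pass. In this list 1 rose, 2 fell and 2 did not pass (1 and 2 adjusted over the list alone) at 12 h, 0 rose, 3 fell and 2 did not pass (0 and 3 adjusted over the list alone) at 180 h, and camera adjusted p was 0.620 at 12 h and 0.248 at 180 h.

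Nitrogenase reduces nitrogen gas and releases hydrogen, and R. palustris encodes molybdenum, vanadium and iron forms, so each was compared over time. Genes of the molybdenum enzyme, already abundant at 0 h in these nitrogen-fixing cells, had risen in part at 12 h. The log2 change then was 2.47 (SE 0.46) for nifK and 1.69 (SE 0.40) for nifD, its catalytic subunits, and 3.05 (SE 0.38) for the ferredoxin fixX. In CPM, nifK went from 3841 ± 943 at 0 h to 21295 ± 6271 at 12 h and 12363 ± 1708 at 180 h (SD, n = 2). The regulator nifA rose by 1.19 at 12 h and 2.46 at 180 h. Of the 32 genes in the molybdenum cluster 26 rose, 0 fell and 6 did not pass (26 and 0 adjusted over the list alone) at 12 h. At 90 h 12 rose, 1 fell and 19 did not pass (10 and 1 adjusted over the list alone), and at 180 h 22 rose, 0 fell and 10 did not pass (21 and 0 adjusted over the list alone). Camera adjusted p was 0.000289 at 12 h, 0.0950 at 30 h, 0.0967 at 50 h, 0.208 at 90 h, 0.0288 at 140 h and 0.00661 at 180 h, and adjusted p = 0.651 at 12 h, 0.687 at 140 h and 0.669 at 180 h with an estimated correlation. The list passed at 30 h without 30 h replicate 1 (adjusted p = 0.00124). The 140 h list call was lost without 140 h replicate 1 (adjusted p = 0.0676). With the list as first matched it also passed at 30, 50 and 90 h (adjusted p = 0.0414, 0.0339 and 0.0262). The iron protein gene nifH, listed as nifH4, rose by 1.07 at 12 h and 1.02 at 180 h, and both calls were lost without single libraries. Its log2 change then stayed close to these values except without 12 h replicate 2. With 1 library left at a time the test has less power. The 12 h call was lost without 0 h replicate 1 (1.09), 0 h replicate 2 (1.02) or 12 h replicate 2 (0.63), and the 180 h call without 0 h replicate 1 (1.06), 0 h replicate 2 (0.99) or 180 h replicate 2 (0.96). The nifD call at 180 h (1.16) was lost without 0 h replicate 2 (0.84) or either 180 h library (1.16 and 1.15). It was also lost with a minimum fold of 1.5, as were both nifH4 calls.

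The vanadium and iron nitrogenase genes were compared in the same way. For the iron enzyme, anfH (RPA1438) went from 5.90 ± 1.11 CPM at 0 h to 79.7 ± 29.1 at 90 h and 1659 ± 273 at 180 h, and its log2 change at 180 h was 8.13 (SE 0.39). The catalytic gene anfD rose by 8.06 (SE 0.40) and its regulator anfA by 5.89 (SE 0.30). For the vanadium enzyme, vnfK rose by 1.47 (SE 0.15) at 12 h, 4.09 (SE 0.15) at 140 h and 4.05 (SE 0.15) at 180 h. In the list of 13 genes 11 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone) at 12 h. At 180 h 13 rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone), with a median log2 change of 1.57, 2.04, 2.50, 3.75, 5.33 and 5.82 in the order of the times. Camera adjusted p was 0.000821 at 12 h and 1.53e-18 at 180 h. With an estimated correlation the list passed at 90, 140 and 180 h (adjusted p = 0.0272, 0.0111 and 0.00863) and not before (adjusted p = 0.305 at 12 h). The 12 h call of anfH (1.02) was lost without each of the 0 and 12 h libraries in turn, with log2 changes between 0.83 and 1.20. It was also lost with a minimum fold of 1.5. Reads shared between the nif, vnf and anf genes would be assigned in a way not given in the sources used here, so the level of any single copy is uncertain.

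**Figure D3:**
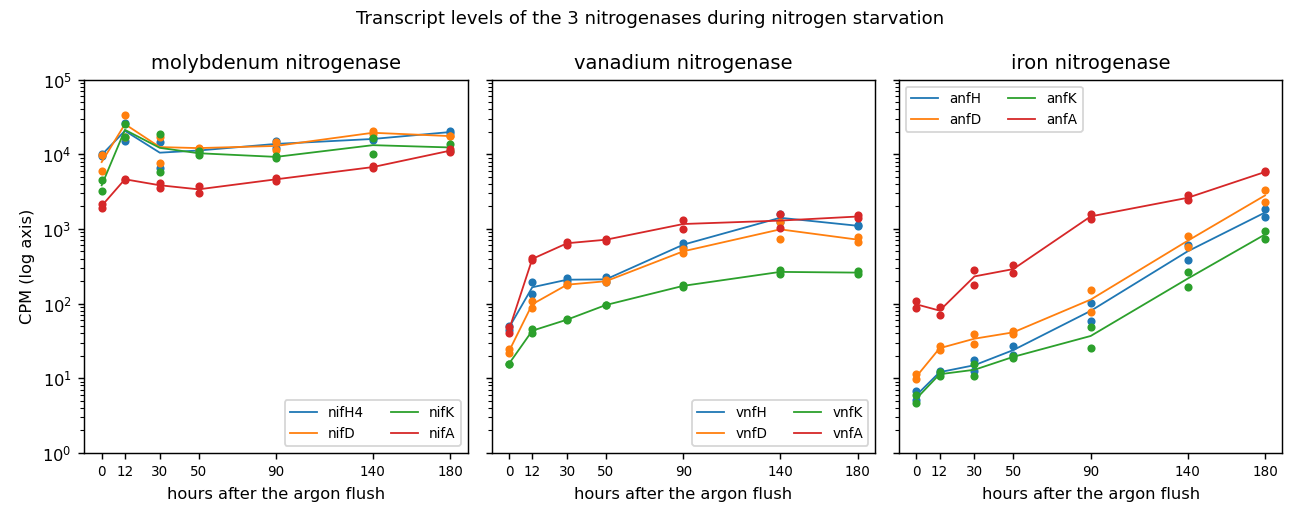
Transcript levels (CPM, log axis) of molybdenum (nif), vanadium (vnf) and iron (anf) nitrogenase genes against hours of nitrogen starvation. Points are the 2 libraries at each time and lines join their means: nifK ends at 12363 CPM, vnfK at 259.5 and anfH at 1659.

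Genes of nitrogen uptake, assimilation and hydrogen oxidation went both ways. The formate/nitrate transporter gene RPA3201 rose by 1.84 (SE 0.27) at 12 h and 6.84 (SE 0.32) at 180 h, while aapP-1, of an amino acid transporter, fell to -3.80 and livM, of a high-affinity branched-chain amino acid transporter, to -2.93 at 180 h. A glutamate transporter gene, RPA1976, fell to -4.03. Of the 112 transporter genes for amino acids, urea and other nitrogen compounds 38 rose, 36 fell and 38 did not pass (38 and 36 adjusted over the list alone) at 12 h. At 180 h 41 rose, 42 fell and 29 did not pass (41 and 42 adjusted over the list alone), with camera adjusted p = 0.585 at 12 h and 0.625 at 180 h. From 12 to 140 h this list had a median above 0 and a mean below 0. In ammonium assimilation and nitrogen regulation, the possible glutamate synthase gene listed as gltA (RPA0678) fell to -2.85 and the urease gene ureC to -2.02 at 180 h. Of its 30 genes 11 rose, 13 fell and 6 did not pass (11 and 13 adjusted over the list alone) at 12 h. At 180 h 14 rose, 12 fell and 4 did not pass (14 and 12 adjusted over the list alone), with camera adjusted p = 0.659 at 12 h and 0.873 at 180 h, and its median and mean differed in sign at 12 and 50 h. The other glutamate synthase gene, RPA4722, fell to -2.58 at 12 h and stood at -0.59 at 180 h. The 180 h call was lost without 0 h replicate 1 (-0.19), 180 h replicate 1 (-0.58) or 180 h replicate 2 (-0.60) and with a minimum fold of 1.5. Among the hydrogenase genes hydC fell to -2.06 and hypA, a maturation gene, to -1.21 at 180 h, while RPA2315 went from 1.36 at 12 h to -1.17 at 180 h. Of 25 hydrogenase genes 9 rose, 6 fell and 10 did not pass (9 and 6 adjusted over the list alone) at 12 h. At 180 h 9 rose, 7 fell and 9 did not pass (9 and 7 adjusted over the list alone), with camera adjusted p = 0.625 at 12 h and 0.905 at 180 h, and at 180 h their median and mean differed in sign.

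The light-harvesting 1 genes pufB (RPA1525) and pufA (RPA1526) fell to -4.59 and -4.62 at 12 h, and pufB went from 19436 ± 1678 CPM at 0 h to 438 ± 11.5 at 180 h (SD, n = 2). Reaction centre genes pufL and pufM fell to -3.96 and -3.02 at 12 h. Of the 16 reaction centre and light-harvesting genes 0 rose, 14 fell and 2 did not pass (0 and 14 adjusted over the list alone) at 12 h. At 180 h 0 rose, 16 fell and 0 did not pass (0 and 16 adjusted over the list alone), with medians of -2.37 at 12 h and -3.88 at 180 h. Camera adjusted p was 7.67e-06 at 12 h and 2.25e-09 at 180 h, or adjusted p = 0.483 and 0.307 with an estimated correlation. In bacteriochlorophyll and carotenoid synthesis, bchD of magnesium chelatase fell to -4.46 at 12 h, and of 27 genes 3 rose, 18 fell and 6 did not pass (3 and 18 adjusted over the list alone) at 12 h. At 180 h 0 rose, 19 fell and 8 did not pass (0 and 19 adjusted over the list alone), with camera adjusted p = 0.000123 at 12 h and 0.000233 at 180 h, and adjusted p = 0.312 and 0.350 with an estimated correlation. ATP synthase gene atpE fell to -3.86 and atpD to -3.03 at 12 h. Of the 10 ATP synthase genes 0 rose, 10 fell and 0 did not pass (0 and 10 adjusted over the list alone) at 12 h. At 180 h 0 rose, 10 fell and 0 did not pass (0 and 10 adjusted over the list alone), with camera adjusted p = 7.41e-07 at 12 h and 7.92e-05 at 180 h, or adjusted p = 0.178 and 0.224 with an estimated correlation. Reads of the near-identical puc antenna genes can be split between copies, so single puc values are uncertain.

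In respiratory complex I, which passes electrons between NADH and quinone, nuoL1 fell to -3.32 and nuoI1 to -2.83 at 12 h, and to -3.32 and -2.81 at 180 h. Of its 28 genes 1 rose, 24 fell and 3 did not pass (1 and 24 adjusted over the list alone) at 12 h. At 180 h 1 rose, 24 fell and 3 did not pass (1 and 24 adjusted over the list alone). It fell at all 6 times both with the preset correlation (camera adjusted p = 1.01e-11 at 12 h and 8.28e-10 at 180 h) and with an estimated one (adjusted p = 0.00848 at 12 h and 0.00848 at 180 h). Cytochrome c2 (cycA), which carries electrons back to the reaction centre, fell to -2.24 at 12 h and RPA1193, cytochrome b/c1, to -2.19, while petA, listed as a Rieske iron-sulfur protein, rose by 1.23. Of the 4 bc1 and c2 genes 1 rose, 3 fell and 0 did not pass (1 and 3 adjusted over the list alone) at 12 h. At 180 h 1 rose, 3 fell and 0 did not pass (1 and 3 adjusted over the list alone), with camera adjusted p = 0.124 at 12 h and 0.212 at 180 h. Among the oxygen-responsive genes the cytochrome oxidase gene coxB rose by 4.25 and coxE, for heme O synthase, by 2.25, while fixG fell to -2.80 and fixQ to -2.19 at 12 h. Of these 19 genes 9 rose, 7 fell and 3 did not pass (9 and 7 adjusted over the list alone) at 12 h. At 180 h 10 rose, 8 fell and 1 did not pass (10 and 8 adjusted over the list alone), with camera adjusted p = 0.462 at 12 h and 0.858 at 180 h. In the Calvin cycle, which fixes carbon dioxide, the form II RuBisCO gene cbbM fell to -2.12 at 12 h and stood at -1.78 at 180 h, and cbbY rose by 1.93 at 180 h. Of its 17 genes 0 rose, 9 fell and 8 did not pass (0 and 9 adjusted over the list alone) at 12 h. At 180 h 3 rose, 10 fell and 4 did not pass (3 and 10 adjusted over the list alone), with camera adjusted p = 0.110 at 12 h and 0.407 at 180 h.

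Ribosomal protein genes rplX (RPA3239) and rplN (RPA3240) fell to -4.81 and -4.74 at 12 h and stood at -3.08 and -3.13 at 180 h. Of 55 ribosomal protein genes 4 rose, 45 fell and 6 did not pass (4 and 45 adjusted over the list alone) at 12 h. At 180 h 10 rose, 34 fell and 11 did not pass (10 and 34 adjusted over the list alone), and the median moved from -2.14 to -1.27. Camera adjusted p was 1.20e-16 at 12 h and 0.000121 at 180 h, or adjusted p = 0.305 and 0.607 with an estimated correlation. Elongation factor Tu (tufA, RPA3252) fell to -4.57 at 12 h and stood at -1.61 at 180 h. RNA polymerase gene rpoC fell to -2.47 at 12 h, with 0.03 at 180 h, where it did not pass. Of 21 translation factor and RNA polymerase genes 1 rose, 13 fell and 7 did not pass (1 and 13 adjusted over the list alone) at 12 h. At 180 h 3 rose, 10 fell and 8 did not pass (3 and 10 adjusted over the list alone). That list fell at 12 h (camera adjusted p = 0.0178, or adjusted p = 0.534 with an estimated correlation) and did not pass at 180 h (0.623); without 0 h replicate 1 the 12 h value was 0.0610. Glycyl-tRNA synthetase gene sygB fell to -2.95 at 12 h and gltX to -2.17 at 180 h. Of 25 aminoacyl-tRNA synthetase genes 5 rose, 16 fell and 4 did not pass (5 and 16 adjusted over the list alone) at 12 h. At 180 h 3 rose, 17 fell and 5 did not pass (3 and 17 adjusted over the list alone). Their camera adjusted p was 0.0529 at 12 h, 0.0346 at 140 h and 0.0189 at 180 h (adjusted p = 0.650 and 0.619 with an estimated correlation at 140 and 180 h), and without 0 h replicate 1 neither late call held (0.0993 and 0.0564). At 12 h that list passed without 0 h replicate 2 (0.0233), 12 h replicate 1 (0.0444), 90 h replicate 1 (0.0451) or 90 h replicate 2 (0.0450).

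In amino acid synthesis metK, for S-adenosylmethionine, fell to -3.38 at 180 h and ilvB, of branched-chain amino acids, to -3.18, while aroG1, the first enzyme of aromatic synthesis, rose by 2.73 at 180 h. Of 88 such genes 22 rose, 40 fell and 26 did not pass (22 and 40 adjusted over the list alone) at 12 h. At 180 h 24 rose, 40 fell and 24 did not pass (24 and 40 adjusted over the list alone), with camera adjusted p = 0.0280 at 12 h and 0.175 at 180 h, and adjusted p = 0.563 at 12 h with an estimated correlation. Fatty acid gene accB fell to -3.53 and fabF to -2.81 at 12 h. Of 16 fatty acid synthesis genes 3 rose, 13 fell and 0 did not pass (3 and 13 adjusted over the list alone) at 12 h. At 180 h 2 rose, 12 fell and 2 did not pass (2 and 12 adjusted over the list alone), with camera adjusted p = 0.0202 at 12 h and 0.0186 at 180 h, or adjusted p = 0.454 and 0.439 with an estimated correlation. Between these times the fatty acid list did not pass at 90 h (0.0551) or 140 h (0.0529) with all libraries. It passed at 30 h (0.0320, or adjusted p = 0.514 with an estimated correlation) and 50 h (0.0284, or adjusted p = 0.483), but not without 0 h replicate 1 (0.0684 and 0.0609). The replication initiator dnaA fell to -3.13, gyrA to -1.45 and the wall synthesis gene murD to -2.88 at 12 h. Of 31 genes of cell division, replication and wall synthesis 5 rose, 15 fell and 11 did not pass (5 and 15 adjusted over the list alone) at 12 h. At 180 h 6 rose, 20 fell and 5 did not pass (6 and 21 adjusted over the list alone). Camera adjusted p for that list was 0.0894 at 12 h and 0.0109 at 180 h, and adjusted p = 0.307 at 180 h with an estimated correlation.

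Neither list of carbon storage genes passed the set test. A polyhydroxybutyrate depolymerase gene, RPA0565, which breaks down the carbon reserve, rose by 1.51 (SE 0.15) at 12 h and 2.43 (SE 0.15) at 180 h. The synthase gene phbC had 0.59 at 12 h, a call lost without 0 h replicate 1 (0.56) or 12 h replicate 2 (0.38), with the 0 and 12 h libraries alone and with a minimum fold of 1.5, and 0.39 at 180 h, where it did not pass except with the 0 and 180 h libraries alone or without 12 h replicate 1. Of the 4 polyhydroxybutyrate genes 3 rose, 0 fell and 1 did not pass (3 and 0 adjusted over the list alone) at 12 h. Of these calls, that of RPA0532, a beta-ketothiolase gene (0.80), was lost without 0 h replicate 2 (0.68) or 12 h replicate 1 (0.46). It was also lost with a minimum fold of 1.5. At 180 h 3 rose, 0 fell and 1 did not pass (3 and 0 adjusted over the list alone). The call of the synthase gene phaC (RPA4243, 0.51) was then lost without 0 h replicate 1 (0.49) or 180 h replicate 2 (0.48). It was also lost with library size alone (0.26) or with a minimum fold of 1.5. The list had camera adjusted p = 0.238 at 12 h and 0.124 at 180 h. Glycogen phosphorylase, listed as glgA2, rose by 1.58 at 12 h and 1.84 at 180 h. Of the 10 glycogen and trehalose genes 3 rose, 2 fell and 5 did not pass (3 and 2 adjusted over the list alone) at 12 h. At 180 h 3 rose, 5 fell and 2 did not pass (3 and 5 adjusted over the list alone), with camera adjusted p = 0.659 at 12 h and 0.679 at 180 h.

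The heat shock sigma factor gene rpoH rose by 2.20 (SE 0.23) at 12 h and 2.61 (SE 0.23) at 180 h, and the catalase gene katE by 1.68 at 12 h and 0.93 at 180 h. The catalase gene katG had a log2 change of 0.44 at 12 h, where it did not pass, and rose by 2.24 at 180 h. Of 18 stress and stationary-phase genes 10 rose, 1 fell and 7 did not pass (9 and 1 adjusted over the list alone) at 12 h. At 180 h 11 rose, 3 fell and 4 did not pass (11 and 3 adjusted over the list alone). Camera adjusted p was 0.0320 at 12 h and 0.0700 at 180 h (adjusted p = 0.651 at 12 h with an estimated correlation), and the 12 h call was lost without 0 h replicate 2 (0.0505), without 12 h replicate 2 (0.103) or with the list as first matched (0.491). The chaperonin genes groEL2 and groEL1 fell to -5.22 and -3.39 at 12 h and stood at -3.22 and -1.76 at 180 h, with reads shared between copies left uncertain. Of 29 chaperone and protease genes 10 rose, 14 fell and 5 did not pass (10 and 14 adjusted over the list alone) at 12 h. At 180 h 13 rose, 12 fell and 4 did not pass (13 and 13 adjusted over the list alone), with camera adjusted p = 0.135 at 12 h and 0.999 at 180 h. The latter list passed at 12 h without 0 h replicate 2 (0.0310). In iron uptake and storage exbB2, which energises uptake, rose by 1.94 and the hemin permease gene RPA0723 fell to -2.25 at 12 h. Of its 63 genes 36 rose, 10 fell and 17 did not pass (36 and 10 adjusted over the list alone) at 12 h. At 180 h 32 rose, 16 fell and 15 did not pass (32 and 16 adjusted over the list alone), with camera adjusted p = 0.0128 at 12 h and 0.0908 at 180 h, and adjusted p = 0.651 at 12 h with an estimated correlation. The iron list passed at 180 h without 0 h replicate 2 (0.0373) or 180 h replicate 2 (0.0467). The chemotaxis genes cheW1-1 and RPA4302 fell to -4.57 and -4.15 at 180 h. Of 87 flagellum and chemotaxis genes 31 rose, 35 fell and 21 did not pass (31 and 36 adjusted over the list alone) at 12 h. At 180 h 13 rose, 54 fell and 20 did not pass (13 and 55 adjusted over the list alone), with camera adjusted p = 0.659 at 12 h and 0.000773 at 180 h, and adjusted p = 0.647 at 180 h with an estimated correlation. Of the 12 tested mobile element and phage genes, the phage-like RPA2566 and RPA2567 fell to -2.69 and -3.46 at 12 h. In that list 7 rose, 2 fell and 3 did not pass (7 and 2 adjusted over the list alone) at 12 h. At 180 h 6 rose, 3 fell and 3 did not pass (6 and 3 adjusted over the list alone), with camera adjusted p = 0.347 at 12 h and 0.547 at 180 h.

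**Figure D4:**
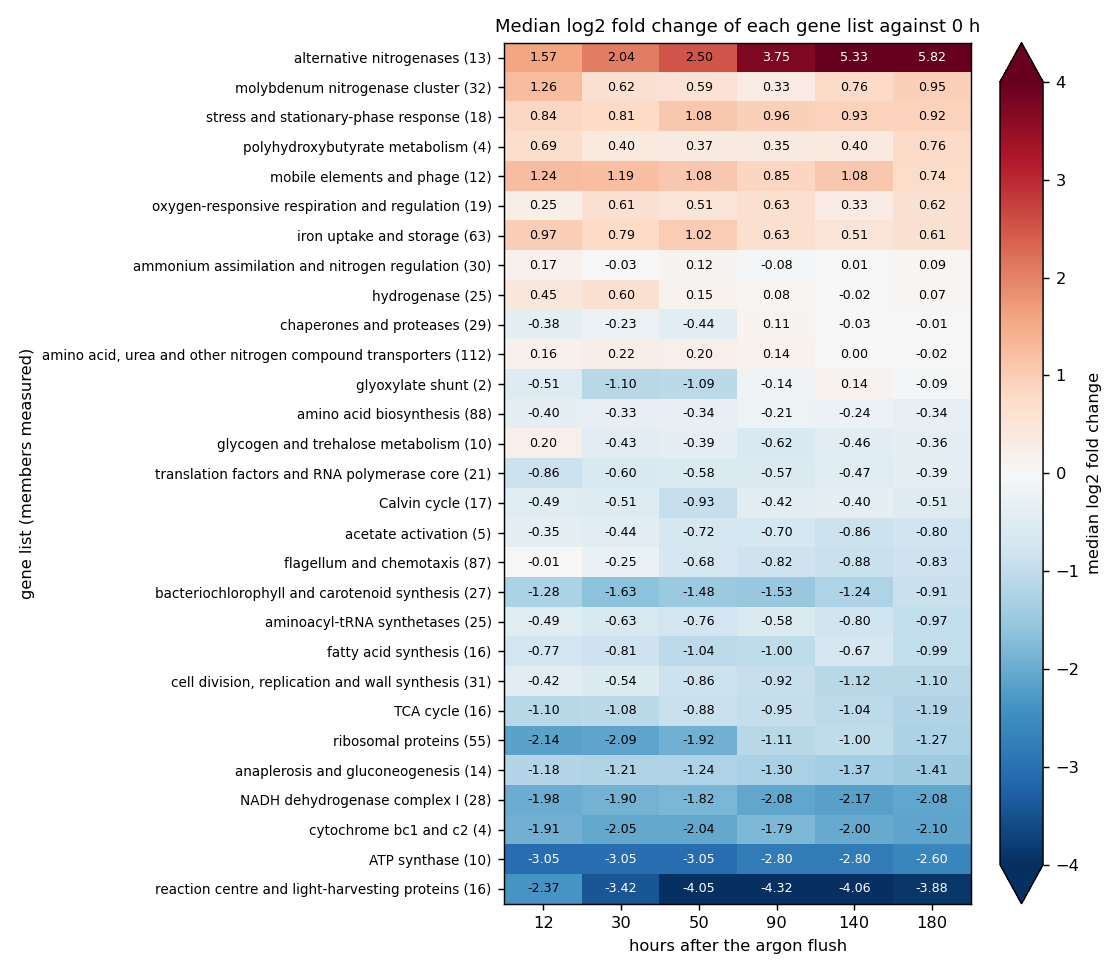
Median log2 change from 0 h (color) of the measured members of each gene list (y axis) at each starved time (x axis). Alternative nitrogenases go from 1.57 at 12 h to 5.82 at 180 h, and the reaction centre and light-harvesting list from -2.37 to -3.88.

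Genes were also named by the size of their change at each time. At 12 h RPA1091, a hypothetical protein gene, rose by 7.64 (SE 1.11), RPA3770 by 5.67 (SE 0.24), RPA2166 by 5.12 (SE 0.38) and RPA0424, listed as a FUR family iron response regulator, by 4.69 (SE 0.41). The largest falls at 12 h were those of RPA1441, a possible uridylate kinase gene (-5.22, SE 0.27), groEL2 (-5.22, SE 0.33) and RPA4057, a possible dolichol phosphate mannose synthase gene (-5.00, SE 0.23). At 30 h RPA3770 (5.83) and RPA1033 (5.50) rose most, and pufA (-6.05) and pufB (-5.92) fell most. At 50 h the largest rises were in RPA3770 (5.87), RPA1375 (5.48) and RPA1386, of a vanadate transporter (5.37), and the largest fall in the antenna gene pucBa (-6.38). At 90 h RPA1386 (7.46), RPA1387 (6.51) and the nitrite reductase gene nirA (5.62) had risen, and pucBc had fallen to -6.18. At 140 h RPA1386 was 8.55 and its neighbour RPA1385, the vanadate binding protein gene, 6.66 above 0 h. At 180 h RPA1386 (9.04, SE 0.31), anfH (8.13), anfD (8.06), RPA3711, a possible sulfite reductase gene (7.92), and nirA (7.75) had the largest rises. RPA1386 was near the floor at 0 h, at 1.10 ± 0.473 CPM (SD, n = 2), so the size of its fold is uncertain. The largest falls at 180 h were those of pucBc (-7.19), pucBd (-6.25), pucAd (-6.09) and RPA2297 (-5.92). For each gene in this paragraph both libraries at that time lay beyond both 0 h libraries.

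The steps between neighbouring starved times ask when expression moved after the first 12 h. From 12 to 30 h 27 genes rose and 67 fell, among them RPA1387 (1.99, SE 0.25) and RPA1386 (1.91, SE 0.24) upward and hpd, of tyrosine breakdown, downward (-2.17, SE 0.33). The calls of RPA1387 and hpd were lost with the 12 and 30 h libraries alone (adjusted p = 0.0941 and 0.146), and that of hpd with a minimum fold of 1.5. From 30 to 50 h 103 rose and 120 fell, among them thiE, of thiamine synthesis (1.63, SE 0.21), and the tmRNA, which rescues stalled ribosomes (-2.68, SE 0.20). The libraries of 30 h replicate 1 and 50 h replicate 2 shared an index tag, which implies that they were sequenced apart. A difference between sequencing pools could therefore add to this step, which was not tested. From 50 to 90 h 199 rose and 103 fell, with anfA (2.35, SE 0.25), groEL2 (2.18, SE 0.29) and RPA1387 (2.12, SE 0.25) rising most. From 90 to 140 h 140 rose and 109 fell, with the tmRNA (3.12, SE 0.21) and anfG (2.93, SE 0.34) up and the cold shock gene cspA2 down (-1.67, SE 0.23). From 140 to 180 h 40 rose and 23 fell, with anfG (2.16, SE 0.31), RPA1434 (2.14, SE 0.29) and anfD (2.02, SE 0.30) up and the tmRNA down (-2.07, SE 0.20). The share of genic reads from tRNA, also a small RNA, was 1.13% ± 0.178 at 12 h, 1.31% ± 0.311 at 30 h, 0.760% ± 0.00670 at 50 h, 0.935% ± 0.0736 at 90 h, 1.45% ± 0.0348 at 140 h and 0.922% ± 0.109 at 180 h (SD, n = 2), so it moved in the same direction as the tmRNA in each of the 3 steps named for it. The calls of anfG, anfD and RPA1434 in the step from 140 to 180 h were lost without 140 h replicate 1 (1.88, 1.79 and 1.79) or 180 h replicate 2 (1.85, 1.73 and 1.97).

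These step counts hung on single libraries, and each moved by over 1.5 times without some of them. The first step had 151 calls without 12 h replicate 1, 19 without 30 h replicate 1, 142 without 30 h replicate 2, 54 to 55 without either 50 h library and 55 without either 180 h library. The 30 to 50 h step had 81 without 30 h replicate 1, 69 without 30 h replicate 2, 15 without 50 h replicate 1, 8 without 50 h replicate 2, 115 without either 140 h library and 92 without either 180 h library. The 50 to 90 h step had 26 without 50 h replicate 1, 50 without 50 h replicate 2, 197 without 90 h replicate 1 and 136 without 90 h replicate 2. The 90 to 140 h step had 123 without 90 h replicate 1, 84 without 90 h replicate 2, 57 without 140 h replicate 1, 35 without 140 h replicate 2 and 164 without either 180 h library. The last step had 5 without 140 h replicate 1, 17 without 140 h replicate 2, 15 without 180 h replicate 1, 4 without 180 h replicate 2, 114 and 119 without the 12 h libraries and 32 and 33 without the 50 h libraries. From libraries at the compared times alone, the 12 to 30 h step had 1 call, the next 2 steps 114 and 179, and the last step 472. With a minimum fold of 1.5 the steps had 4, 4, 19, 17 and 10 calls in order, and with DESeq2 the first had 211 and the last 159. With library size alone, the share of calls that were higher moved by over 10 points in every step but that from 30 to 50 h, and 140 h had 71 genes higher and 600 lower than 90 h.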

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

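All the tests of explanations in this part were chosen only after the results they bear on were seen. Intergenic reads, which the comparisons of genes do not use, took a larger share after starvation: 22.8% ± 0.312 at 0 h (SD, n = 2), and 26.1% at 12 h, 27.7% at 30 h, 28.0% at 50 h, 29.0% at 90 h, 27.6% at 140 h and 27.3% at 180 h. Of 2917 stretches of at least 50 bases, 814 were higher and 837 lower at 12 h than at 0 h by the edgeR quasi-likelihood test. The counts higher and lower were 739 and 979 at 30 h, 747 and 996 at 50 h, 865 and 886 at 90 h, and 959 and 837 at 140 h. Up to 90 h, then, the larger share did not come with more stretches higher than lower. At 180 h 917 were higher and 817 lower, and 162 were higher while both neighbouring genes had a log2 change below 1. Among these, the stretch between RPA0712 and RPA0713 rose by 3.13, that between RPA2523 and RPA2524 by 2.89, that between RPA2593 (ntrC) and RPA2594 (ntrY) by 2.86, and that between RPA2924 (dnaE) and RPA2925 by 2.68. No biological explanation of these was tested.

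Between 0 h and 12 h 3335 genes differed, and at most 302 between later neighbouring times. Index tags used again on libraries of different times imply that the libraries sharing a tag were sequenced apart, so a difference between sequencing pools could add to the gap. The largest median absolute log2 difference between starved libraries sharing a tag was 0.519 times the smallest between 0 h and 12 h libraries (0.25 to 0.41 over 4 pairs, against 0.79 to 0.87). This argues against a pool difference of the size seen among starved libraries as the whole cause. No 0 h library was in these pairs, so a pool that set the 0 h libraries apart was not tested. Each pair joined a 12 or 30 h library with a 50 or 90 h library. A pool difference could therefore also add to the step from 30 to 50 h, which was not tested. A few abundant transcripts moving the scale would shift all other genes by the same amount and leave the spread of log2 differences over genes unmoved. The smallest interquartile range of these between 0 h and 12 h libraries was 2.70 times the largest between libraries of neighbouring starved times (1.54 against 0.57), which argues against a moved scale as the whole cause. The response to nitrogen loss stays open as a hypothesis, along with anything else that differed between the 0 h cells or libraries and all starved ones.

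The median of the alternative nitrogenase genes climbed until 180 h. Reads shared with the abundant molybdenum nitrogenase genes could raise them, but nifH, nifD and nifK had a median log2 change of -0.45 from 12 h to 180 h, while that of the 8 alternative subunit genes was 4.52. A shortage of molybdate that raises its uptake genes could raise them too, but the 4 genes listed for molybdate transport went both ways from 0 h to 180 h (median log2 change -0.65): modA, modB and modC had -0.52, -0.77 and -1.29, modD rose by 1.83, and the regulator gene modE beside modA rose by 3.67. So a molybdate shortage stays open, as does a response to prolonged nitrogen starvation itself, which was not tested.

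The share of genic reads from rnpB went from 1.60% at 0 h to 7.72% at 180 h, and its log2 change was 2.52 (SE 0.27). A shrinking messenger RNA pool could leave stable RNAs with a larger share, which would raise the tmRNA and the 4.5S RNA gene ffs alike. Both rose less than rnpB: the smaller of their changes was 0.23 (SE 0.19, ffs), against 1.44 for the tmRNA. The tRNA share of genic reads went from 0.519% at 0 h to 0.922% at 180 h. How well small RNAs were recovered is not known, so these values cannot decide the question. Without rnpB in the library sizes, the median log2 change of all genes moved by at most 0.04. A shrinking messenger RNA pool and a change in rnpB RNA itself both stay open, the latter untested.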

How the results depend on the processing

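Library size alone, tests without rnpB, the lists as first matched, list tests with 1 library left out and the exact permutation test of the pathway difference, and that difference with each shunt gene alone, were chosen after seeing the data. None of the named gene values past the threshold changed direction under any alternative, and other genes were not checked for this. Nor did any gene list test past the threshold under the alternatives run for lists. These were an estimated correlation, fry, a replicate block, the lists as first matched and each library left out. With glcB alone as the shunt, the difference between TCA cycle and shunt turned positive at 12, 90, 140 and 180 h (0.11, 0.14, 0.34 and 0.25), and with aceA alone it was -1.42, -1.88, -2.62 and -2.28. At 30 and 50 h, where it was near 0, it changed sign under some alternatives. With RLE scaling, no filter, the strict filter and without rnpB, all counts of genes stayed within 1.5 times their values. Under a minimum fold of 1.5, a stricter question, 1102 genes were higher and 1088 lower at 12 h. At 30 h 1141 were higher and 1163 lower, and the steps had 4, 4, 19, 17 and 10 calls in order. DESeq2 gave 211 calls from 12 to 30 h and 159 from 140 to 180 h. The compared libraries alone gave 1, 114 and 179 in the first steps and 472 in the last. Library size alone gave 671 from 90 to 140 h. Except for the minimum fold, the cause was not tested. The median absolute log2 difference between replicates was 0.22 at 12 h and 0.21 at 30 h, but 0.14 at 140 h and 0.12 at 180 h. The reported fit shares its estimate of spread over all times, so its SE does not follow such differences between times. With 1 library left out, the lone library is assumed to vary like the others. The steps then had 19 to 151, 8 to 306, 26 to 363, 35 to 354 and 4 to 119 calls in order, and the difference between TCA cycle and shunt was -0.93 to -0.38 at 12 h, -0.26 to 0.30 at 30 h, -0.26 to 0.29 at 50 h, -1.15 to -0.60 at 90 h, -1.41 to -0.86 at 140 h and -1.29 to -0.74 at 180 h. As a ratio of summed CPM it was -1.20 at 12 h, -1.83 at 90 h, -2.30 at 140 h and -2.11 at 180 h, and with the lists as first matched -1.19, -0.95, -1.19, -1.59, -1.48 and -1.36 in order. Its exact permutation test over all times did not pass with glcB alone (p = 0.178). It passed with aceA alone, the ratio of summed CPM, the lists as first matched and each library left out. It also passed with library size alone, but a library's scaling factor nearly cancels in a difference taken within that library. That pass was therefore close to fixed in advance. The permutation test was not run under the other alternatives. Of 168 list tests 73 passed, 9 with an estimated correlation and 144 with fry, a different question, and 63 to 82 with 1 library left out. Of 427 tested values of named genes, 41 lost their call without some library, 59 with the minimum fold, 15 with the compared libraries alone, 10 with library size alone and 1 with DESeq2. These 427 values include some that did not pass with all libraries, such as aceA at 12 h, and such values have no call to lose. The median reads per gene were 234 or more in every library. Whether depth or the number of libraries limits the calls more was not tested.

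In the check of pairing, the differences between replicates of 1 time correlated over 4014 genes with those of another at over 0.1 in 12 of 21 pairs of times (range -0.13 to 0.37). Among 50, 90, 140 and 180 h every pair did (0.18 to 0.37), as did 12 h with 30 h (0.35), so some replicates with the same number deviate together. The numbers were taken to pair the samples only if every pair did, which was not so, and the reported fit, without a block, was fixed beforehand. With a replicate block the counts were 206 from 12 to 30 h (54 up and 152 down, against 27 and 67) and 97 from 140 to 180 h, and the other counts stayed within 1.5 times. The cause was not tested.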

Other observations

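The genes in this paragraph were chosen after their values were seen. Next to the vanadium nitrogenase genes, RPA1385 and RPA1384, listed as parts of a vanadate transporter, had log2 changes of 2.54 and 0.38 at 12 h (the latter did not pass) and 6.95 (SE 0.31) and 4.14 (SE 0.18) at 180 h. Beside the iron nitrogenase genes, RPA1432, RPA1433 and RPA1434 did not pass at 12 h and rose by 5.33 (SE 0.26), 6.01 (SE 0.30) and 6.67 (SE 0.40) at 180 h. In the molybdate operon modE, of the regulator, rose by 3.67 (SE 0.25) at 180 h, while modC, of the transporter, fell to -1.29. The nitrate transporter genes nrtA and nrtB rose by 2.66 and 2.84 at 12 h, did not pass at 50 h (0.42 and 0.76), and were 2.39 and 2.79 higher at 180 h. RPA3709, a possible hemoprotein gene beside nirA, rose by 6.03 (SE 0.57). The genes of an ABC transporter, RPA2677, RPA2678 and RPA2679, rose by 7.03, 5.16 and 4.97 at 180 h, and those of NAD synthesis, nadA, nadB and nadC, by 5.58, 4.90 and 2.52. The tmRNA went up and down, with log2 changes from 0 h of 2.88 at 12 h, 0.01 at 50 h, 3.51 at 140 h and 1.44 at 180 h, the one at 50 h not past the test. The tRNA share of genic reads went up and down with it, at 0.519% at 0 h, 1.13% at 12 h, 0.760% at 50 h, 1.45% at 140 h and 0.922% at 180 h, so how well small RNAs were recovered is not separated from a change in the tmRNA.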
